A study of Mus musculus with 12 samples.

How the data were processed

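The data were 12 bulk RNA-seq libraries of sorted mouse intraepithelial lymphocytes (IEL), with 3 libraries in each of 4 groups. Groups were taken from the sample titles and from the labels for cell type and progeny. The extraction protocol in the labels names an RNA purification kit and a library kit, and does not say whether the kit kept strand. The deposited table held whole-number read counts per gene, made by the authors from aligned reads and not normalised. Reads were aligned with HISAT2 2.1.0 to the mm10 mouse genome, per the submitters' processing notes. The program that counted reads, its annotation release and its treatment of strand and of reads with several matches are not given in the sources used here. Reads of genes with near-identical copies, such as processed pseudogenes or members of the Klra, Ly6, Hspa1 and H2 families, are therefore uncertain, and so are overlapping and antisense genes.

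The table had 25965 rows with 25899 different symbols. Where rows shared a symbol, the row with the highest total was used, which left out 66 rows holding 0.0202% of the reads. Ensembl identifiers of 25035 rows were found in the GENCODE M21 annotation of mm10. Of these, 100% lay on the same chromosome and 99.8% overlapped the annotated gene, so coordinates are given in mm10. Rows of T cell receptor constant regions were not analysed here. The 13 rows of mitochondrially encoded genes held 0 reads, so a list of these genes could not be tested and the share of mitochondrial reads was not used as a sign of RNA quality.

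Library totals ran from 5620257 to 11070734 counts, and 12838 to 14085 genes had at least 1 count. A count of 0 in a library allows a level of up to 3 counts, which is 0.271 to 0.534 CPM at these totals. For a gene with 0 reads in a whole group, the fold is given as a lower bound computed against 3 counts over the group. For a gene with 1 to 3 reads in a group, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only. Levels are CPM of the deposited counts over the TMM-scaled library total, as mean ± SD of 3 libraries, while the floors in CPM use the unscaled total of a library and the bounds of folds the scaled totals of a group.

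Replicates were compared before they were averaged. Over genes with at least 20 reads in a pair, the chi-square per gene between libraries of a group was 11.4 to 60.9, so no pair agreed within sampling noise, as repeated sequencing of 1 library would, and each library counted as 1 replicate. This does not show that they came from separate animals. Within groups, the correlation of log2 CPM across genes was 0.926 to 0.968.

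Genes were kept by the edgeR function filterByExpr (minimum count 10, minimum total 15), which left 12622 genes. Counts were scaled by TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes tested. All 12 libraries entered a single model with 1 mean per group, so the 4 groups shared their estimate of spread. Genes were called at adjusted p under 0.05. The 4 pairwise comparisons were CD8αα from CD4 against CD4 IEL, CD8αα from CD8αβ against CD8αβ IEL, CD8αα from CD4 against CD8αα from CD8αβ, and CD4 IEL against CD8αβ IEL. A test of the difference between the first 2 changes (interaction) and a test of any difference among the 4 groups used the same model. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and beside it with an estimated correlation and with fry. There were 30 lists of T cell lineage, effector, receptor, metabolic and stress genes and of markers of other cell types that the gate could hold. The CD8 lineage list held Cd8a and Cd8b1 and the CD4 helper lineage list Cd4, on whose proteins the cells were sorted. Sorting thus fixed part of the results of these lists. List p-values were adjusted over the lists within a comparison, and called members are also given adjusted over the list alone.

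The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took 3 kinds of gene per comparison. The first were Cd4, Cd8a, Cd8b1, Zbtb7b, Runx3 and Themis. The second were the 6 called genes with the largest rise and the 6 with the largest fall. These were taken among genes whose libraries did not overlap between the groups and whose mean in the higher group was above the median of tested genes. With 3 libraries against 3, chance alone leaves 10% of genes with no overlap. For genes taken this way no overlap was a condition, so a later statement of it is no further evidence. No overlap condition was set for the interaction, and predicted genes, small RNAs and receptor segments were left out. The third were up to 2 called members of each list with the largest absolute log2 fold change. Any other gene named was chosen after its values were seen, and the text says so.

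The test was first tried on simulated counts drawn from the real means and library sizes. For CD8αα from CD4 against CD4 IEL it recovered 9.23%, 46.2% and 75.4% of 65 genes each changed 1.5, 2 and 4 times, with 3 false calls among 12324 genes. For CD8αα from CD4 against CD8αα from CD8αβ it recovered 4.62%, 40% and 76.9%, with 4 false calls. In simulated data for CD8αα from CD4 against CD4 IEL, camera gave a changed set an adjusted p of 1.44e-26 and called 0 of 29 random sets over 12622 genes. Each gene was drawn independently, so this does not test false calls for lists whose members vary together. Estimated correlations in the real data were 0.787 for the interferon list, 0.583 for the epithelium list and 0.249 for the cell cycle list.

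Alternatives fixed beforehand were DESeq2 size factors, DESeq2 1.42.0 and limma-voom in place of edgeR, no filter on low counts and a stricter filter (minimum count 40, total 60), all rows in place of 1 per symbol, only the libraries compared, stricter thresholds (absolute log2 fold change of at least 1, or adjusted p under 0.01), replicate number as a block, and leaving out each of the 12 libraries in turn. Figures were drawn with matplotlib 3.10.9.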

Results

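RNA was sequenced from IEL of the small intestine of Rag2-deficient mice, which make no T or B cells of their own, 1 week after intravenous transfer of conventional T cells from lymph nodes of Themis wild-type donors. Hosts given CD4 T cells yielded TCRβ CD4 cells (CD4 IEL) and TCRβ CD8αα cells (CD8αα from CD4). Hosts given CD8αβ T cells yielded TCRβ CD8αβ cells (CD8αβ IEL) and TCRβ CD8αα cells (CD8αα from CD8αβ). The series title concerns how CD8αα IEL that arise from CD4 T cells differ from those that arise from CD8 T cells. Each group had 3 libraries. Totals were 6381733 to 8595847 counts in CD4 IEL, 5620257 to 8876202 in CD8αα from CD4, 6099918 to 9443881 in CD8αβ IEL and 9313173 to 11070734 in CD8αα from CD8αβ. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples. Principal component 1 held 52.5% of the variance of log2 CPM and component 2 held 18.2%.

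Transcripts of the coreceptors followed the labels, while the genes of the T cell receptor constant regions, which the TCRβ label concerns, were not analysed here. Cd4 (ENSMUSG00000023274, chromosome 6 of mm10, 124864692 to 124888221) was at 1642 ± 93.1 CPM (SD, n = 3) in CD4 IEL, 2.94 ± 0.359 in CD8αα from CD4, 23.2 ± 16.6 in CD8αβ IEL and 6.95 ± 3.02 in CD8αα from CD8αβ. Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379171), the chain shared by both CD8 forms, was at 47.2 ± 1.40, 2650.5 ± 200.2, 2161 ± 70.7 and 2968 ± 257 CPM in the same order. Cd8b1 (ENSMUSG00000053044, chromosome 6, 71322836 to 71337477), the β chain absent from CD8αα dimers, was at 5.05 ± 1.70, 17.5 ± 2.77, 1124 ± 40.1 and 2.95 ± 0.471 CPM. Because the cells were sorted on these 3 proteins, the differences check the labels and are not findings.

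**Figure D1:**
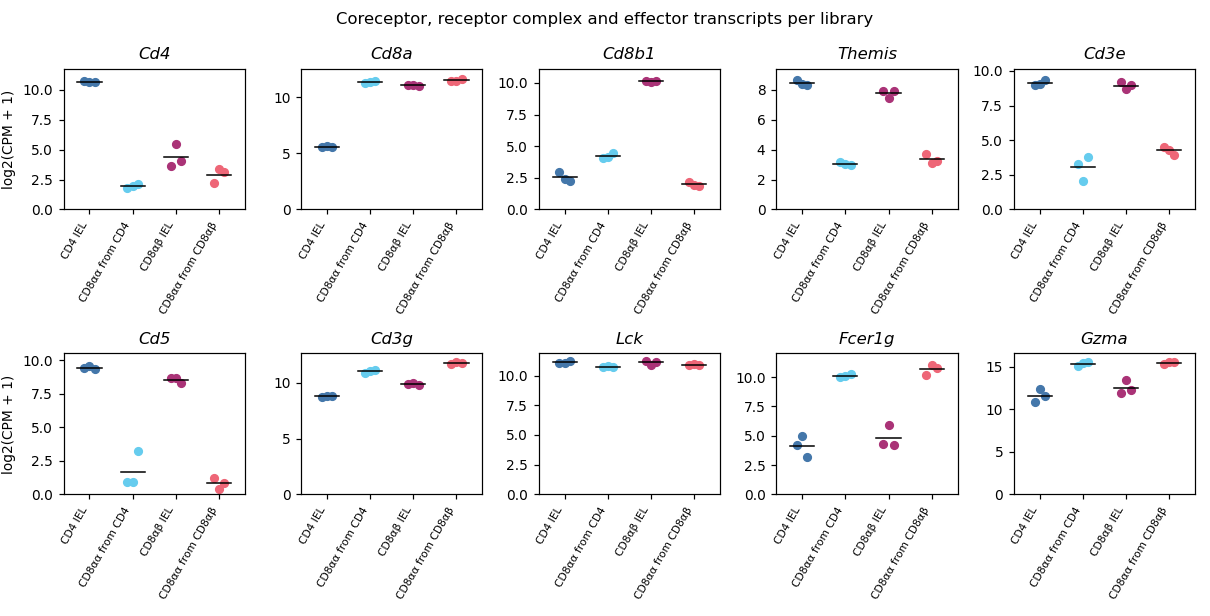
Level of 10 transcripts in each library as log2(CPM + 1), with 1 point per library (3 per group) and a black bar at the mean of 3. Cd8b1 was high only in CD8αβ IEL, and Themis, Cd3e and Cd5 were lower in all 6 libraries labelled CD8αα than in the other 6, while Fcer1g and Gzma were higher.

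Themis (ENSMUSG00000049109, chromosome 10, 28668360 to 28883818), a T cell protein needed for thymic selection, was at 354 ± 48.8 CPM in CD4 IEL and 220.1 ± 38.4 in CD8αβ IEL, against 7.31 ± 0.501 in CD8αα from CD4 and 9.39 ± 2.49 in CD8αα from CD8αβ. Other genes of the T cell receptor complex and surface, chosen after their values were seen, had the same pattern. Across the 6 CD4 IEL and CD8αβ IEL libraries Cd3e was at 403 to 639 CPM, Cd5 at 311 to 740.2, Cd2 at 118 to 302 and Bcl11b at 183 to 512. In the 6 libraries labelled CD8αα these were 3.21 to 22.2, 0.319 to 8.43, 0.115 to 2.56 and 8.02 to 23.1 CPM. Cd3d and Cd247, of the same complex, were at 2.58 to 12.1% and 3.51 to 10.1% of the companion group's mean (CD4 IEL or CD8αβ IEL) in the libraries labelled CD8αα, although the label names TCRβ. Cd3g ran the other way, with 424 to 1002 CPM in the CD4 IEL and CD8αβ IEL libraries and 1902 to 3780.5 in those labelled CD8αα. The kinase gene Lck was at 1938 to 2478 and 1671 to 2007 CPM.

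Sex-linked transcripts did not follow the groups. All 6 CD4 IEL and CD8αβ IEL libraries had Y-linked transcripts (Ddx3y, Eif2s3y, Kdm5d and Uty together at 234 to 449 CPM), with the X-inactivation transcript Xist at 0 to 36.4 CPM. Of the 6 libraries labelled CD8αα, 4 had Xist at 373 to 645 CPM and Y-linked transcripts at 0.342 to 1.03 CPM: replicates 1 and 2 of CD8αα from CD4 and replicates 1 and 3 of CD8αα from CD8αβ. Replicate 3 of CD8αα from CD4 and replicate 2 of CD8αα from CD8αβ had Y-linked transcripts at 363 and 321 CPM and Xist at 1.25 and 0.850 CPM. The words progeny, rose and fell below follow the labels and do not mean that transferred T cells changed.

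**Figure D2:**
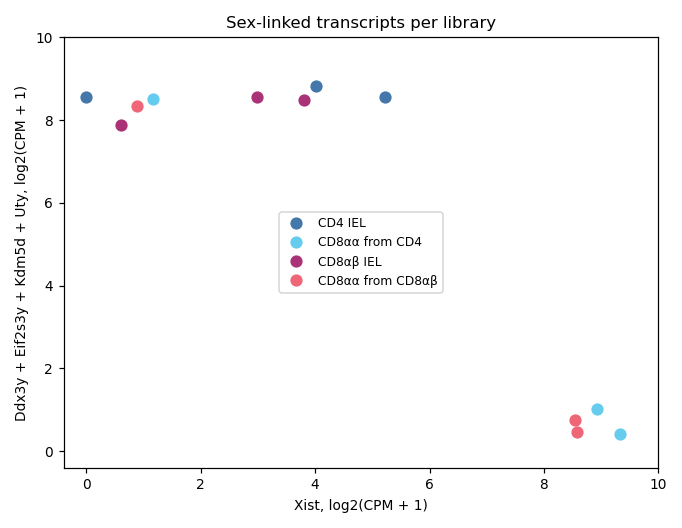
Xist (x axis) against the sum of 4 Y-linked transcripts (y axis), both as log2(CPM + 1), with 1 point for each of the 12 libraries coloured by group. The 4 points at lower right are libraries labelled CD8αα, and the other 8 libraries lie at upper left.

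In the CD4 progeny, libraries labelled CD8αα had lower transcripts of T helper, naive T cell and T cell receptor signalling genes than CD4 IEL, and higher transcripts of natural killer (NK) receptors, of the natural IEL signature and of the granzyme gene Gzma. Cd28 (ENSMUSG00000026012, chromosome 1, 60716800 to 60773359), a costimulatory receptor, was at 582 ± 122 CPM in CD4 IEL and 1.79 ± 1.48 in CD8αα from CD4 (log2 fold change −8.40 ± 0.48 SE, edgeR adjusted p = 5.50e-08). Gzma (ENSMUSG00000023132, chromosome 13, 113093825 to 113100979), of cytotoxic granules, was at 3362 ± 1689 and 41962 ± 7354 CPM (3.64 ± 0.40 SE, edgeR adjusted p = 1.46e-05). It took 3.50 to 4.70% of the counts of each library labelled CD8αα and 0.197 to 1.09% of the others. Themis fell (edgeR adjusted p = 6.03e-09), with all 3 libraries below all 3 of CD4 IEL.

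By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3597 of 12622 genes differed between CD8αα from CD4 and CD4 IEL (1898 higher and 1699 lower). Scaling by library totals alone turned this split to 1650 and 2017. Of the called lists, 5 were higher and 16 lower, and 12 of these 21 held with an estimated correlation. All 13 tested members of the Th17 list fell, 13 adjusted over the list alone (median log2 fold change −7.11, or −6.68 with members of few reads at their bound, camera adjusted p = 3.70e-13). Il22 (ENSMUSG00000074695, chromosome 10, 118204942 to 118210047), a cytokine that acts on epithelium, was at 213 ± 88.8 CPM in CD4 IEL, and 1 read in CD8αα from CD4 gave a ratio of 4306 (counting interval 773 to 170121). The chemokine receptor gene Ccr6 and Il21 had 0 reads in CD8αα from CD4, at least 276-fold and at least 336-fold lower. Of 10 CD4 helper lineage genes 9 fell (0 and 9 adjusted over the list alone; camera adjusted p = 8.28e-10), among them Cd4, on which the cells were sorted, and Tnfsf11, at least 358-fold lower. Of 17 naive and recirculating T cell genes 12 fell and 1 rose (2 and 12 adjusted over the list alone; camera adjusted p = 2.33e-07), with Slamf6, an adhesion receptor, at −7.74. In the T cell receptor signalling list 23 of 36 members fell and 3 rose (4 and 25 adjusted over the list alone; camera adjusted p = 1.31e-09), led by Ubash3a (−9.60), a phosphatase that restrains receptor signalling.

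The 5 higher lists were NK receptors, the natural IEL signature, cytotoxicity, CD8 lineage genes and intestinal epithelium, while the list of NK cell and innate lymphoid genes was not called (camera adjusted p = 0.641; 6 up and 7 down of 16). Of 25 NK receptor genes 17 rose and 2 fell (17 and 3 adjusted over the list alone), with a median of 3.94 (camera adjusted p = 3.82e-07). The Klra receptor genes share sequence, and Klra8 had 0 reads in CD4 IEL, so its rise was at least 32.9-fold. The natural IEL signature had 19 members up and 2 down (19 and 3 adjusted over the list alone; camera adjusted p = 1.31e-09), with Klra7 at 6.50 and Spry1, an inhibitor of growth factor signalling, at least 69.0-fold lower. In the cytotoxicity list 11 of 15 members rose and 3 fell (11 and 3 adjusted over the list alone; camera adjusted p = 4.66e-04), a call that did not hold at adjusted p = 0.0534 with an estimated correlation. Of 10 CD8 lineage genes 7 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.00691; adjusted p = 0.0867 with an estimated correlation). Cd8a and Cd8b1, on which the cells were sorted, were among those that rose. Zbtb16, the gene of the innate-type regulator PLZF, rose by 5.94 ± 0.77 SE (edgeR adjusted p = 6.56e-05) and Tcf7, the gene of TCF-1, fell (−6.64). Runx3, which promotes CD8 lineage genes, was at 0.50 (edgeR adjusted p = 0.0184), and its call ended at adjusted p 0.0959, 0.0520 and 0.0539 without CD4 IEL replicate 1 and without CD8αα from CD4 replicates 2 and 3. Zbtb7b, which directs CD4 fate, did not pass the test (−0.42, edgeR adjusted p = 0.304).

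The lists of cell cycle genes, cytokines and chemokines, cytokine receptors, chemokine and homing receptors and stress genes were also lower in CD8αα from CD4. Of 40 cell cycle genes 34 fell (0 and 36 adjusted over the list alone; median −1.55, camera adjusted p = 6.45e-17), among them Ccnb2 (−2.70) and E2f2 (−3.32). Of 25 cytokines and chemokines 18 fell and 4 rose (4 and 19 adjusted over the list alone; camera adjusted p = 4.59e-08). Of 26 cytokine receptors 18 fell and 2 rose (2 and 19 adjusted over the list alone; camera adjusted p = 9.40e-08), with Il18r1, a chain of the interleukin 18 receptor, at least 644-fold lower. Of 29 chemokine and homing receptors 19 fell and 5 rose (5 and 20 adjusted over the list alone; camera adjusted p = 1.17e-07). Of 25 immediate early and dissociation stress genes 18 fell (0 and 19 adjusted over the list alone; camera adjusted p = 1.86e-09), with the phosphatase gene Dusp2 at −4.31. The epithelial adhesion gene Epcam was at 4.90 ± 2.80 CPM in CD4 IEL and 100.4 ± 5.43 in CD8αα from CD4, and the epithelium list was higher (median 1.07, 2 of 27 members up, 2 and 0 adjusted over the list alone, camera adjusted p = 0.00231; adjusted p = 0.486 with an estimated correlation). That list call ended without CD4 IEL replicate 3 (0.0628). The myeloid list was not called (camera adjusted p = 0.372; 6 up and 1 down of 22), although the Fc receptor gene Fcgr3 rose (5.17). With only the 2 libraries labelled CD8αα that had Y-linked transcripts, 1 per origin, 1280 genes were called.

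In the CD8αβ progeny, libraries labelled CD8αα had lower transcripts of cell cycle, naive T cell, homing receptor and T cell receptor signalling genes than CD8αβ IEL, and higher transcripts of the natural IEL signature and of cholesterol genes. The calls of the T cell receptor signalling, natural IEL and cholesterol lists were lost with an estimated correlation (adjusted p = 0.0958, 0.117 and 0.0958). Cd5 (ENSMUSG00000024669, chromosome 19, 10718143 to 10738974), a surface receptor that dampens T cell receptor signals, was at 368 ± 49.2 CPM in CD8αβ IEL and 0.811 ± 0.495 in CD8αα from CD8αβ (log2 fold change −8.77 ± 0.65 SE, edgeR adjusted p = 3.18e-07). Fcer1g (ENSMUSG00000058715, chromosome 1, 171229572 to 171234365), the signalling chain of Fc receptors, was at 31.5 ± 23.2 and 1684 ± 469 CPM (5.72 ± 0.53 SE, edgeR adjusted p = 2.57e-06). Pdcd1, which encodes the inhibitory receptor PD-1, was at 377 ± 91.0 and 0.926 ± 0.171 CPM (−8.63 ± 0.47 SE, edgeR adjusted p = 2.52e-08). Each of these had all 3 libraries of one group above all 3 of the other.

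In this comparison 3939 genes were called (2030 higher and 1909 lower; edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and the split was 1859 and 2090 with library totals alone and 1926 and 2031 with DESeq2 size factors. Of the 13 called lists 3 were higher, and 5 of the 13 held with an estimated correlation. Of 40 cell cycle genes 39 fell (0 and 39 adjusted over the list alone; median −2.32, camera adjusted p = 1.61e-24), with Ube2c at −3.69 and Ccnb1 at −3.54. Of 17 naive and recirculating T cell genes 16 fell (0 and 16 adjusted over the list alone; camera adjusted p = 1.71e-10). S1pr1, a receptor for exit from tissue, had 2 reads in CD8αα from CD8αβ, a ratio of 908 (counting interval 251 to 7503). Of 29 chemokine and homing receptors 23 fell and 3 rose (4 and 23 adjusted over the list alone; camera adjusted p = 7.79e-08). In the T cell receptor signalling list 21 of 36 members fell and 5 rose (5 and 21 adjusted over the list alone; camera adjusted p = 6.58e-07; adjusted p = 0.0958 with an estimated correlation), with Cd2 at −8.98 and Ubash3a at −9.21. Of 10 CD4 helper lineage genes 8 fell and 2 rose (2 and 8 adjusted over the list alone; camera adjusted p = 1.94e-04), including Cd28 (−8.23).

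Higher in CD8αα from CD8αβ were 16 of 23 members of the natural IEL signature, with 1 lower (16 and 2 adjusted over the list alone; camera adjusted p = 2.61e-07; adjusted p = 0.117 with an estimated correlation). Of 25 genes of lipid and cholesterol metabolism 14 rose (14 and 1 adjusted over the list alone; camera adjusted p = 0.00431; adjusted p = 0.0958 with an estimated correlation), among them Hmgcs1, an enzyme of sterol synthesis (1.62). NK receptor genes had 15 members up and 6 down (15 and 7 adjusted over the list alone), and their list call (camera adjusted p = 0.0241; adjusted p = 0.407 with an estimated correlation) ended without each of 5 libraries. These were CD8αβ IEL replicate 1 (0.0983), CD4 IEL replicate 3 (0.0569), CD8αα from CD4 replicate 3 (0.0557) and CD8αα from CD8αβ replicates 2 (0.0629) and 3 (0.0756). The CD8 lineage list was not called, and its median (0.36) and mean (−1.87) differed in sign (4 members up and 4 down of 10, camera direction lower, adjusted p = 0.400). Interferon-stimulated genes fell for 15 of 30 members (0 and 18 adjusted over the list alone; camera adjusted p = 1.61e-04; adjusted p = 0.525 with an estimated correlation). Zbtb16 rose (5.92), Tcf7 fell (−5.25), and Runx3 (0.67) was higher, as was Zbtb7b, at 5.10 ± 2.43 CPM in CD8αβ IEL and 14.2 ± 0.492 in CD8αα from CD8αβ. Epcam was at 34.2 ± 19.2 and 207 ± 24.3 CPM, while the epithelium list (4 of 27 up, camera adjusted p = 0.833) and the myeloid list (4 up and 11 down of 22, adjusted p = 0.0695) were not called. With only the libraries labelled CD8αα that had Y-linked transcripts, 1421 genes were called.

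The CD8αα changes of the 2 progenies, which shared no library, were set side by side. Genes called in both in the same direction numbered 2266, of which 1195 were higher and 1071 lower, and 41 were called in opposite directions. With library totals alone the split was 1062 and 1228. Independent lists of these sizes would share 305 higher, 257 lower and 560 opposite genes. The log2 fold changes had Pearson r = 0.72 and Spearman rho = 0.62 across genes, which are not independent replicates. In both progenies some libraries labelled CD8αα, 4 of the 6 in all, also differed from both companion groups in sex-linked transcripts. With only the libraries labelled CD8αα that had Y-linked transcripts, 781 genes were shared and r was 0.57. Cd8b1 was among the 41, with 1.76 in the CD4 progeny and −8.56 in the CD8αβ progeny, on which the latter cells were sorted. Tox2, linked to T cell exhaustion and follicular helper cells, fell in both, with 2 reads in each CD8αα group (ratios 1071, interval 296 to 8852, and 389, interval 107 to 3217). Folr4, a receptor gene of regulatory T cells, had 0 reads in either CD8αα group, at least 117-fold and at least 179.8-fold lower.

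**Figure D3:**
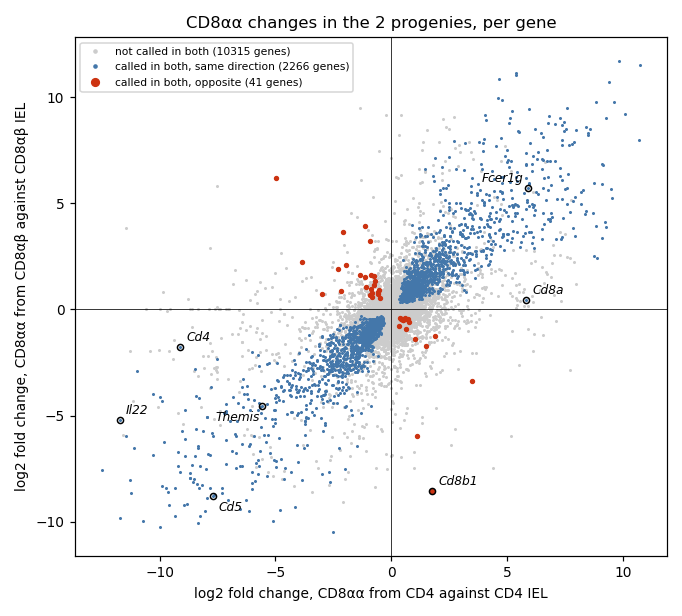
Fitted log2 fold change of each of 12622 genes in CD8αα from CD4 against CD4 IEL (x axis) and in CD8αα from CD8αβ against CD8αβ IEL (y axis). Blue points are the 2266 genes called in both in the same direction, red points the 41 called in opposite directions and grey points all others, and fitted values of genes with few reads are no bounds.

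Between the libraries labelled CD8αα, those of the CD4 progeny had higher transcripts of the costimulatory receptor Icos, the integrin chain Itga4 and the NK receptor Klra7, and lower transcripts of stress genes, Nr4a1 among them, and of interferon-stimulated genes than those of the CD8αβ progeny. Of the 7 called lists 0 held with an estimated correlation (stress adjusted p = 0.153, interferon 0.506). This is the comparison that the series title names. Icos (ENSMUSG00000026009, chromosome 1, 60977927 to 61000320) was at 9.45 ± 2.64 CPM in CD8αα from CD4 and 0.682 ± 0.198 in CD8αα from CD8αβ (log2 fold change 3.75 ± 0.34 SE, edgeR adjusted p = 1.28e-04). Both levels were small beside 514 to 585 CPM in CD4 IEL and 131 to 230 in CD8αβ IEL. In CD8αα from CD4, Cd4 was at 0.156 to 0.200% and Cd28 at 0.0985 to 0.590% of the CD4 IEL mean. Il18r1 had 0 reads there and 2164 in CD4 IEL. Icos kept a larger part of its CD4 IEL level than these, which argues against traces of whole CD4 IEL as its main source. Themis (1.94 to 2.22%) and Thy1 (0.874 to 3.39%) kept parts nearer that of Icos. Whether a subset of companion cells held the Icos transcripts was not tested. Itga4, which pairs in gut-homing integrins, was at 50.6 ± 5.78 and 10.4 ± 2.90 CPM (2.27 ± 0.21 SE, edgeR adjusted p = 1.46e-04). Nr4a1 (ENSMUSG00000023034, chromosome 15, 101266846 to 101274792), an immediate early gene of T cell receptor signalling and a member of the stress list, was at 265 ± 12.7 and 914 ± 67.2 CPM (−1.79 ± 0.13 SE, edgeR adjusted p = 4.71e-05). In each of the 3, no library of one group overlapped the other. Themis (−0.37, edgeR adjusted p = 0.392), Cd8a (−0.16, 0.435), Runx3 (0.06, 0.872) and Zbtb7b (0.35, 0.575) did not pass the test.

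Here 547 genes were called (236 higher and 311 lower in CD8αα from CD4; edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and library totals alone turned the split to 314 and 223. The count was 166 without CD8αα from CD4 replicate 1, 192 without replicate 2, 181 without CD8αα from CD8αβ replicate 2 and 182 without replicate 3. It was 1036 with DESeq2, 959 with only the groups compared in the fit and 1 with only the 2 libraries that had Y-linked transcripts, 1 per group. Among 43 called genes taken by the rule, 24 calls ended when 1 library was left out, and the genes named here kept theirs unless stated. Klra7 (ENSMUSG00000067599, chromosome 6, 130218605 to 130233322) was at 80.3 ± 33.4 and 7.79 ± 1.27 CPM (3.36 ± 0.58 SE, edgeR adjusted p = 0.00694), in a family whose reads are uncertain. Of 25 NK receptor genes 7 rose and 0 fell (11 and 2 adjusted over the list alone; median 0.98, camera adjusted p = 1.54e-04; adjusted p = 0.297 with an estimated correlation). Higher genes with the largest changes also included Bcl3, a nuclear factor κB regulator (2.51), the kinase gene Pim2 (1.92) and Adam19 (1.92). Members of lists that were not called included Il7r, the interleukin 7 receptor chain (2.02), Gzmk (1.68), Ctla4 (1.70) and Il18rap (3.87), all higher in CD8αα from CD4. Il4ra (−1.39) and Tnfsf8 (−2.44) were lower. Il7r was at 8.02 to 18.7 CPM in CD8αα from CD4, a small part of the 383 to 613 CPM in CD4 IEL. As for Icos, this part was larger than that of Cd4, and a subset of companion cells was not tested as its source. Of 36 T cell receptor signalling genes 1 rose and 2 fell (3 and 5 adjusted over the list alone), and that list was not called (camera adjusted p = 0.995).

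Of the 7 called lists 6 were lower in CD8αα from CD4, among them stress, interferon and cell cycle genes. Of 25 immediate early and dissociation stress genes 11 fell (0 and 17 adjusted over the list alone; median −0.85, camera adjusted p = 8.45e-11; adjusted p = 0.153 with an estimated correlation). Atf3 (−3.07) and Hspa1a (−2.62), which shares near-identical sequence with Hspa1b, were among them. Tissue digestion and sorting also raise genes of this list. The labels give no day or host, so handling cannot be told apart from the progeny. Of 30 interferon-stimulated genes 14 fell (0 and 22 adjusted over the list alone; median −1.75, camera adjusted p = 2.40e-09; adjusted p = 0.506 with an estimated correlation). Ifit3 (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731), an antiviral gene, was at 4.28 ± 0.925 and 71.6 ± 73.1 CPM (−4.08, edgeR adjusted p = 0.0173). Its call ended without CD8αα from CD4 replicates 1, 2 and 3 (0.0856, 0.0908 and 0.0516) and without CD8αα from CD8αβ replicate 3 (0.0746). Of 40 cell cycle genes 4 fell (0 and 9 adjusted over the list alone; camera adjusted p = 1.69e-05; adjusted p = 0.446 with an estimated correlation). Of 25 cytokines and chemokines 6 fell and 1 rose (1 and 8 adjusted over the list alone; camera adjusted p = 0.0202; adjusted p = 0.297 with an estimated correlation), a call that ended without CD8αα from CD4 replicate 1 (0.0527). In the glycolysis list 0 of 20 members passed the test over all genes (0 and 4 adjusted over the list alone; camera adjusted p = 0.0288; adjusted p = 0.297 with an estimated correlation). That call ended without CD8αα from CD4 replicates 1 (0.0790) and 3 (0.122) and without CD8αα from CD8αβ replicates 1 (0.0931) and 3 (0.0529).

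CD4 IEL differed from CD8αβ IEL in T helper 17 genes and helper lineage genes, which were higher, and in cytotoxic, cell cycle and interferon-stimulated genes, which were lower. Of these list calls the helper lineage call held with an estimated correlation, and the others did not (Th17 adjusted p = 0.0607, cytotoxicity and cell cycle 0.144, interferon 0.460). Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496), the signature cytokine of Th17 cells, was at 188 ± 71.3 CPM in CD4 IEL and 1.24 ± 1.79 in CD8αβ IEL (log2 fold change 7.44 ± 0.71 SE, edgeR adjusted p = 5.89e-05). Il22 was at 213 ± 88.8 and 2.05 ± 1.91 CPM (6.82 ± 0.66 SE, edgeR adjusted p = 3.60e-05). Ly6c2 (ENSMUSG00000022584, chromosome 15, 75108160 to 75111684), a surface antigen of effector and memory CD8 cells with close relatives in the genome, was at 5.89 ± 4.38 and 276 ± 114 CPM (−5.51 ± 0.49 SE, edgeR adjusted p = 2.15e-05). In each, all 3 libraries of one group were above all 3 of the other. Themis was higher in CD4 IEL (0.69, edgeR adjusted p = 0.0130), a call that ended without CD4 IEL replicate 1 (0.0562) or CD8αβ IEL replicate 2 (0.0507).

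The test called 3655 genes (1630 higher and 2025 lower in CD4 IEL; edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and scaling by library totals alone turned this split to 2309 and 1724. Of the 10 called lists 4 were higher, and 1 of the 10 held with an estimated correlation. Of 13 Th17 genes 11 rose (11 and 0 adjusted over the list alone; median 4.48, camera adjusted p = 1.60e-09; adjusted p = 0.0607 with an estimated correlation), with Il17f, at 0 reads in CD8αβ IEL, at least 120.3-fold higher. Of 10 CD4 helper lineage genes 8 rose (8 and 0 adjusted over the list alone; camera adjusted p = 4.25e-06; held at adjusted p = 0.0217 with an estimated correlation), among them Cd40lg (5.16), the ligand that helps B cells. This list also held Cd4, on which the cells were sorted. Of 26 cytokine receptors 14 rose and 3 fell (14 and 3 adjusted over the list alone; camera adjusted p = 2.62e-04; adjusted p = 0.108 with an estimated correlation), with Il17re at least 315-fold higher. Of 10 Th2 genes 4 rose (5 and 0 adjusted over the list alone; camera adjusted p = 0.00265; adjusted p = 0.205 with an estimated correlation). Podnl1 (5.78), the interleukin 12 receptor gene Il12rb2 (4.93), the aryl hydrocarbon receptor gene Ahr (2.52) and Zbtb7b (2.27) were also higher.

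Of 40 cell cycle genes 34 fell in CD4 IEL relative to CD8αβ IEL (0 and 36 adjusted over the list alone; camera adjusted p = 3.08e-12; adjusted p = 0.144 with an estimated correlation), with Stmn1 at −2.44. Of 15 cytotoxicity genes 10 fell and 2 rose (3 and 11 adjusted over the list alone; camera adjusted p = 0.00145; adjusted p = 0.144 with an estimated correlation), among them Gzmk (from 473 ± 74.8 CPM in CD8αβ IEL to 118 ± 23.0 in CD4 IEL) and Crtam (−2.03). Of 10 CD8 lineage genes 8 fell (1 and 8 adjusted over the list alone; camera adjusted p = 6.53e-06; adjusted p = 0.0607 with an estimated correlation), Cd8a and Cd8b1 included. Of 30 interferon-stimulated genes 20 fell (0 and 23 adjusted over the list alone; median −1.71, camera adjusted p = 4.95e-06; adjusted p = 0.460 with an estimated correlation), with Ifit3 at 21.2 ± 12.2 and 344 ± 234 CPM and Usp18 at −3.86. The epithelium and myeloid lists were lower as well. Of 27 epithelium genes 10 fell (0 and 11 adjusted over the list alone; median −1.84, camera adjusted p = 8.19e-04; adjusted p = 0.475 with an estimated correlation). Of 22 myeloid genes 8 fell and 1 rose (1 and 10 adjusted over the list alone; camera adjusted p = 0.0234; adjusted p = 0.475 with an estimated correlation), a call that ended without CD4 IEL replicate 3 (0.161) or CD8αβ IEL replicate 2 (0.0803). The large differences of Ppia (−5.68) and Rps6 (−4.96), which have many near-identical copies, rested on CD8αβ IEL replicate 1, without which they were −1.21 and −0.98 (edgeR adjusted p = 0.00813 and 0.0153).

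**Figure D4:**
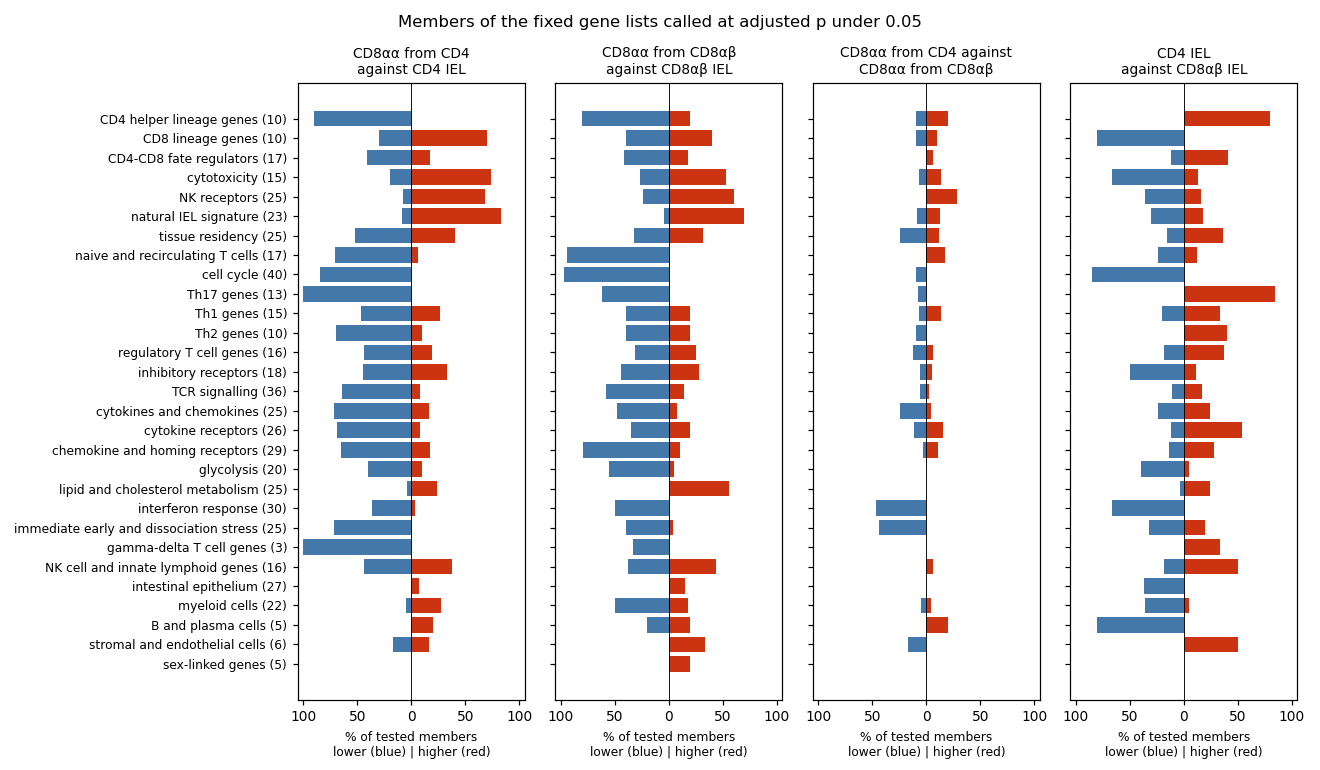
Percent of the tested members of each gene list that were higher (red, to the right) or lower (blue, to the left) at edgeR adjusted p under 0.05 in the 4 pairwise comparisons, with the number of members tested in brackets. The natural IEL signature lies mostly to the right and the cell cycle list to the left in both comparisons of CD8αα with its companion group.

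The difference between CD4 IEL and CD8αβ IEL was set beside that between the libraries labelled CD8αα. Of the 3655 genes that differed between CD4 IEL and CD8αβ IEL, 335 (9.17%) differed in the same direction between CD8αα from CD4 and CD8αα from CD8αβ, with 138 higher and 197 lower, and 26 were called in the opposite direction. Independent lists of these sizes would share 30.5 higher, 49.9 lower and 78.0 opposite genes, and no library entered both comparisons. The 2 comparisons are still not independent if libraries of a progeny share a host or day, or hold traces of each other's cells. The labels give no host or day, so the overlap cannot tell these apart from the origin of the cells. The count was 93 without CD8αα from CD4 replicate 1, 117 without replicate 2, 109 without CD8αα from CD8αβ replicate 2, 107 without replicate 3 and 204 without CD4 IEL replicate 2. It was 652 with DESeq2 and 1 with only the libraries labelled CD8αα that had Y-linked transcripts, and library totals alone turned the split to 210 higher and 135 lower. Whether called or not, 83.5% of the 3655 genes (3052) had the same sign in both, with a median signed log2 fold change of 0.37 between the CD8αα groups against a median size of 1.06 between CD4 IEL and CD8αβ IEL. The share with the same sign over all tested genes was not computed. Over all 12622 genes the log2 fold changes of the 2 comparisons had Pearson r = 0.29 and Spearman rho = 0.46. Trat1, an adaptor of the T cell receptor complex, was higher in the CD4 progeny in both (1.76 and 1.92), and its second call ended without CD8αα from CD8αβ replicate 3 (0.0591). Xcl1, a chemokine gene of CD8 and NK cells, was lower in both (−2.57 and −2.76), with the second call lost without CD8αα from CD4 replicate 1 (0.0550). Gzmk and Tnfsf8 differed in opposite directions: Gzmk was lower in CD4 IEL than in CD8αβ IEL (edgeR adjusted p = 5.88e-05) and higher in CD8αα from CD4 than in CD8αα from CD8αβ (1.68). Tnfsf8, the ligand of CD30, was higher in CD4 IEL (3.31) and lower in CD8αα from CD4 (−2.44). In CPM, Tnfsf8 was at 98.9 ± 33.8 in CD4 IEL, 23.6 ± 11.6 in CD8αα from CD4, 10.1 ± 3.66 in CD8αβ IEL and 127 ± 17.1 in CD8αα from CD8αβ.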

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

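The interaction test, which asks whether the change from the companion group to CD8αα differed between the CD4 and CD8αβ progenies, and its count of regroupings were chosen before the result was seen, and the Y-linked restriction and the block within each progeny were tests chosen after it. The difference is the log2 change in the CD4 progeny minus that in the CD8αβ progeny. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 323 genes (152 above 0 and 171 below). Of 100 regroupings of the 12 libraries, 1, the real one, gave a count this large, and the highest of the others was 188. The other regroupings mixed libraries of the real groups, which also differ in other ways than this, and their common dispersion (0.229 to 0.400) lay above the real one (0.0791), so they do not test this difference alone and chance was not excluded. The count was 200 without CD4 IEL replicate 2, 161 and 147 without CD8αα from CD4 replicates 2 and 3, and 156 and 175 without CD8αα from CD8αβ replicates 1 and 3. It was 817 with DESeq2, 13 with only the libraries labelled CD8αα that had Y-linked transcripts, and 500 with the replicate number as a block within each progeny, and the regroupings did not keep same-numbered libraries together. Groups had 3 libraries each and were not searched for single outlying libraries.

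The coreceptor genes were called, as sorting fixed: Cd8b1 (10.32), Cd8a (5.35) and Cd4 (−7.34). They also count as members of the CD8 lineage and CD4 helper lineage lists below. Of the NK receptor list 6 members were above 0 and 3 below (9 and 5 adjusted over the list alone). Among those above 0 were Klrc1 (7.09), Klre1 (5.55) and Klrk1 (5.32), whose mean levels were lower in CD8αα from CD8αβ than in CD8αβ IEL and higher in CD8αα from CD4 than in CD4 IEL. Klrk1, the gene of the activating receptor NKG2D, was at 97.5 ± 57.3 CPM in CD8αβ IEL and 3.94 ± 1.82 in CD8αα from CD8αβ. Cytotoxic and effector genes above 0 were Gzmk (3.68), Crtam (3.61) and the chemokine gene Ccl3 (2.27). Also above 0 were S100a6 (4.26), the costimulatory receptor Cd27 (2.40), the inhibitory receptors Klrg1 (2.99) and Havcr2 (2.50), the integrin Itga4 (2.58), the receptor chain Cd3d (1.44) and the protease Adamts14 (7.28). The cell cycle genes Ube2c (1.84) and Tk1 (1.75) and the class II genes H2-Aa (3.23) and H2-Eb1 (3.15) were above 0 too.

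Of the CD4 helper lineage list 1 member was above 0 and 3 were below (1 and 3 adjusted over the list alone). Single genes below 0 were Tnfsf8 (−5.75), the transcription factors Maf (−5.28), Ahr (−1.82), Runx1 (−1.83) and Zbtb7b (−1.92), and the receptors Il12rb2 (−5.06) and Il4ra (−1.62). Il12rb2 was at 739 ± 218 CPM in CD4 IEL, 24.2 ± 6.81 in CD8αβ IEL and 342 ± 36.9 and 376 ± 20.5 in CD8αα from CD4 and from CD8αβ. The immediate early genes Nr4a1 (−1.52), Egr2 (−1.71) and Jun (−1.61) were below 0. Tgfb3 (−3.36), the signalling inhibitor Socs2 (−1.66), the adaptor Pag1 (−1.30), the hexokinase Hk2 (−2.32), Pecam1 (−2.19) and Tmem176b (−4.02) were also below 0. A septin gene whose symbol stands in the table as Sep-08 (ENSMUSG00000018398, chromosome 11) was at −5.23. For 5 genes a group had 3 or fewer reads, so no difference in fold is given, and edgeR adjusted p was 0.0190 for Il17re, 0.0203 for Klrb1b, 0.0108 for Il23r, 0.0340 for Csf2 and 0.0121 for Col1a2.

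Among the 42 genes called and named, 19 calls ended when 1 library was left out. By the library that gave the highest edgeR adjusted p, these were, without CD8αα from CD4 replicate 3, Zbtb7b (0.0865), Runx1 (0.0626), Socs2 (0.0607), Klrb1b (0.0599), Tk1 (0.119), Ube2c (0.132), Havcr2 (0.0630), Klrg1 (0.114) and H2-Aa (0.0997). Without CD8αα from CD4 replicate 2 they were Pag1 (0.0924), Egr2 (0.0595), Jun (0.0887), Ahr (0.0551) and Csf2 (0.1003). Without CD8αα from CD8αβ replicate 1 they were Cd3d (0.108) and Klre1 (0.0629), and without its replicate 2 they were Il17re (0.999826), Tmem176b (0.0765) and Il23r (0.0623). Each of the other 8 libraries also ended at least 2 of these calls.

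Of the gene lists, 16 were called for the difference, and 8 of them held with an estimated correlation. The difference equals that between the CD8αα groups minus that between CD4 IEL and CD8αβ IEL. In this order, medians were 0.05 and −2.02 for CD8 lineage genes and −0.01 and −0.78 for cytotoxicity. They were 0.35 and 2.07 for CD4 helper lineage genes and −0.53 and −1.84 for epithelium, mainly a difference of the companion groups. The first was larger in size for stress (−0.85 and −0.18), NK receptor (0.98 and −0.27), stromal, lipid, and cytokine and chemokine genes. Brackets give the median, the called members above and below 0 over all genes and, after "alone", those adjusted over the list alone. Higher medians were found for CD8 lineage genes (2.77, 6 and 0, alone 6 and 0), cytotoxicity (0.78, 5 and 0, alone 9 and 0), NK receptors (0.61, 6 and 3, alone 9 and 5), cell cycle (0.55, 5 and 0, alone 12 and 0), intestinal epithelium (1.59, 0 and 0 of 27, alone 0 and 0), myeloid cells (1.97, 3 and 0, alone 6 and 0) and B and plasma cells (2.57, 0 and 0 of 5, alone 1 and 0). Lower medians were found for CD4 helper lineage genes (−1.42, 1 and 3, alone 1 and 3), Th17 genes (−3.58, 0 and 3, alone 0 and 4), Th2 genes (−1.63, 0 and 1, alone 0 and 1), regulatory T cell genes (−0.60, 0 and 1, alone 1 and 4), cytokines and chemokines (−0.63, 3 and 3, alone 4 and 4), cytokine receptors (−0.75, 0 and 7, alone 1 and 8), lipid and cholesterol metabolism (−0.19, 0 and 0 of 25, alone 0 and 8), immediate early and dissociation stress (−0.76, 0 and 6, alone 0 and 13) and stromal and endothelial cells (−2.28, 0 and 2, alone 0 and 2). Without genes that had 3 or fewer reads in a group, medians were 2.22 for CD8 lineage genes, −0.57 for CD4 helper lineage genes, −3.18 for Th17 genes, −1.62 for Th2 genes, −0.55 for regulatory T cell genes, −0.29 for cytokines and chemokines, −0.34 for cytokine receptors, 1.73 for myeloid cells, 1.80 for B and plasma cells and −1.81 for stromal and endothelial cells. The calls lost with an estimated correlation had these values: NK receptors adjusted p = 0.152 with an estimated correlation, cell cycle 0.152, Th2 genes 0.0543, lipid and cholesterol metabolism 0.110, stress 0.0846, epithelium 0.496, myeloid cells 0.321 and B and plasma cells 0.102. The epithelium call ended without CD4 IEL replicate 3 (0.0776), CD8αβ IEL replicate 2 (0.0800) or CD8αα from CD8αβ replicate 1 (0.0937), and the B and plasma cell call without the same 3 libraries (0.0525, 0.0800 and 0.0527).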

How the results depend on the processing

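Library totals alone, thinned counts, edgeR's newer dispersion method and robust moderation, the replicate block within each progeny, the restriction to libraries labelled CD8αα with Y-linked transcripts and leaving out genes with a named pseudogene were tests chosen only after the data were seen. Of 266 called results for named genes, 147 stayed called with the same direction under every alternative and 119 were lost at least once. The Y-linked restriction lost 103 of them, adjusted p under 0.01 lost 57 and limma-voom lost 34. Of 67 called lists, 25 stayed called under every alternative. With an estimated correlation 26 lists were called and with fry 87. Depth limited what 0 reads in a single library allow to 0.271 to 0.534 CPM, while the bounds of folds used 3 counts over the 3 libraries of a group.

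With DESeq2 the counts were 1036 for CD8αα from CD4 against CD8αα from CD8αβ, 817 for the interaction and 652 for the difference of the progenies seen both between CD4 IEL and CD8αβ IEL and between the CD8αα groups (the repeated progeny difference), and the cause was not tested. With only the groups compared, CD8αα from CD4 against CD8αα from CD8αβ gave 959, and the cause was not tested. With only the libraries labelled CD8αα that had Y-linked transcripts, the fit had 1 such library per origin, whose spread was assumed to be like that of the other groups. Counts were then 1280 and 1421 for CD8αα against CD4 IEL and against CD8αβ IEL, 1 between the CD8αα groups, 13 for the interaction, 3413 for any difference, 781 for the shared change (r = 0.57 against 0.72) and 1 for the repeated progeny difference. Fewer libraries entered this fit, and 3 results changed direction. Xist in CD8αα from CD8αβ against CD8αβ IEL was −2.96, the T cell receptor signalling list between the CD8αα groups had an adjusted p of 0.0498, and the epithelium list for the interaction one of 0.861.

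An absolute log2 fold change of at least 1 left 2189, 2530, 293 and 1965 genes in the 4 pairwise comparisons, 1479 for the shared change and 125 for the repeated progeny difference. Adjusted p under 0.01 left 2276, 2528, 143 and 1886 genes, 98 for the interaction, 1474 for the shared change and 70 for the repeated progeny difference. Both ask more of each gene by construction. Leaving out 1 library gave 2768 to 3913 genes for CD8αα from CD4 against CD4 IEL, 3128 to 4086 for CD8αα from CD8αβ against CD8αβ IEL, 166 to 714 between the CD8αα groups and 2649 to 3764 for CD4 IEL against CD8αβ IEL. The ranges were 147 to 368 for the interaction, 5954 to 6632 for any difference (6587 with all libraries), 1923 to 2382 for the shared change, 93 to 382 for the repeated progeny difference and 63 to 69 for called lists.

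Scaling by library totals alone moved the median of all genes in CD4 IEL against CD8αβ IEL from 0.01 to 0.13. It moved the share of higher calls there from 44.6% to 57.3%, between the CD8αα groups from 43.1% to 58.5% (314 higher and 223 lower) and for the repeated progeny difference from 41.2% to 60.9% (210 and 135). The split also turned for CD8αα from CD4 against CD4 IEL (1650 higher and 2017 lower), for CD8αα from CD8αβ against CD8αβ IEL (1859 and 2090) and for the shared change (1062 and 1228), and not for the interaction. Over all alternatives the split turned in 3 of 29, 10 of 29, 2 of 28 and 1 of 28 for the 4 pairwise comparisons, 6 of 28 for the interaction, 4 of 28 for the shared change and 4 of 27 for the repeated progeny difference. For CD4 IEL against CD8αβ IEL the single turn was that with library totals alone, and the split was 744 and 1221 at an absolute log2 fold change of at least 1 and 697 and 1189 at adjusted p under 0.01. The medians of all 67 called lists kept their sign under every scaling tried.

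The labels do not say what a replicate number shares, so the main fit did not pair the samples by it. Of 18 pairs of same-numbered libraries, 2 had a correlation of deviations over 0.1 (range −0.069 to 0.326), and 11 correlated best with their own number. Within progenies 5 of 6 pairs correlated best with their own number (−0.016 to 0.060 in the CD4 progeny and 0.098 to 0.326 in the CD8αβ progeny), a hint from the data that libraries of a progeny with the same number may share a source. With the number as a replicate block, counts were 3674, 3941, 663 and 3814 in the pairwise comparisons, 356 for the interaction, 6623 for any difference, 2294 for the shared change, 433 for the repeated progeny difference and 67 for lists. The replicate block within each progeny gave 500 for the interaction, and the cause was not tested. The pseudocount and quantile alternatives apply to normalised values only and were not run, and the fit to the groups compared has no form for the interaction.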

Other observations

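The tests of the 3 patterns below were chosen only after the result was seen, and the counts of regroupings before it. Several further immune genes, chosen after their values were seen, separated the 6 libraries labelled CD8αα from the 6 CD4 IEL and CD8αβ IEL libraries with no overlap. The kinase genes Syk and Lyn, which serve Fc and innate receptors, were higher, with Syk at 189.5 to 323 CPM against 1.39 to 17.6 and Lyn at 67.8 to 154 against 0.899 to 45.6. So were the adaptor Tyrobp (1428 to 3036 against 24.0 to 165), the NK receptor Klrb1c (164 to 342 against 7.08 to 19.5), the surface protein Cd7 (5222 to 8670.2 against 258 to 1354) and the interleukin 15 receptor chain Il2rb (3352 to 3939 against 679 to 889). Itgae, the αE chain of the integrin that binds epithelial E-cadherin, was at 3818 to 4521 against 1486 to 2330.4 CPM, and Gzmb at 12110.0 to 20070.0 against 1748 to 4332. Lower were Thy1 (0.804 to 6.66 against 157 to 231), Lat (30.5 to 56.0 against 749 to 1201) and Cd6 (2.66 to 18.9 against 774 to 1955). Eomes was at 0 to 0.748 CPM and Ncr1 at 0 to 4.27 in the libraries labelled CD8αα, and Ncr1 overlapped its level in the other libraries (0 to 7.18).

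Further lists are given here with the members that rose and fell, the first of them again. In CD8αα from CD4 against CD4 IEL, NK cell and innate lymphoid genes had 6 members up and 7 down of 16 (6 and 7 adjusted over the list alone; camera adjusted p = 0.641, not called), and tissue residency genes 10 up and 13 down of 25 (10 and 13 adjusted over the list alone; camera adjusted p = 0.405, not called). Inhibitory receptors had 6 up and 8 down of 18 (6 and 8 adjusted over the list alone; camera adjusted p = 0.320, not called), with Pdcd1 at −7.29. Th2 genes fell for 7 of 10 members and rose for 1 (1 and 7 adjusted over the list alone; camera adjusted p = 5.08e-04; adjusted p = 0.0680 with an estimated correlation). Regulatory T cell genes fell for 7 of 16 members and rose for 3 (3 and 7 adjusted over the list alone; camera adjusted p = 0.00193; adjusted p = 0.0429 with an estimated correlation). Interferon-stimulated genes fell for 11 of 30 and rose for 1 (1 and 14 adjusted over the list alone; camera adjusted p = 7.43e-04; adjusted p = 0.486 with an estimated correlation), with Ly6a at −5.07. Between the CD8αα groups, the stromal list was lower in CD8αα from CD4 (1 of 6 members fell, 0 and 2 adjusted over the list alone; camera adjusted p = 0.0449; adjusted p = 0.297 with an estimated correlation). That call ended without CD8αα from CD4 replicates 1 (0.0790) and 2 (0.0659) and without CD8αα from CD8αβ replicate 3 (0.183). In CD8αα from CD8αβ against CD8αβ IEL, glycolysis genes fell for 11 of 20 members and rose for 1 (1 and 11 adjusted over the list alone; camera adjusted p = 0.00787; adjusted p = 0.132 with an estimated correlation). Of their named members, Pgk1 was at −1.88, and −0.75 without CD8αβ IEL replicate 1.

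Transcripts of several genes of the T cell surface were nearly absent from the libraries labelled CD8αα in both progenies (Cd2 at 0.115 to 2.56 CPM against 118 to 302). Of the receptor complex and its adaptor, Cd3e, Cd3d, Cd247 and Lat were at 0.576 to 12.1% of the companion group's mean and Cd3g at 349 to 523%. Low RNA amount or quality was argued against, since Ptprc, Lck and Zap70 stayed at 67.1% or more of the companion group's mean in each of these libraries. The test for exchanged labels used Cd5 (lowest 311 CPM in CD4 IEL and CD8αβ IEL), which is part of the pattern and so restates it. The coreceptors argue against exchanged labels. Cd4 was at 1583 to 1749 CPM in CD4 IEL and 2.56 to 3.28 in CD8αα from CD4. Cd8b1 was at 1087 to 1167 CPM in CD8αβ IEL and 2.53 to 3.46 in CD8αα from CD8αβ. In the 4 libraries with Xist, Y-linked transcripts were at most 0.286% of the mean of the CD4 IEL and CD8αβ IEL libraries, which is consistent with cells from another animal than the one that gave those IEL. RNA of the host is a candidate source of these, although the TCRβ gate should remove host lymphocytes. In these 4 libraries the values argue against a change of T cells from the animals that gave the CD4 IEL and CD8αβ IEL. The labels do not give the sex of donors or hosts, nor whether the same donors gave both cell types. In the 2 libraries with Y-linked transcripts (lowest 89.0%) another animal cannot be told apart, since animals of the same sex give the same values. These 2 also had low Cd3e (12.8 and 18.9 CPM) and Cd5 (8.43 and 0.319 CPM). For them a true change of the transferred T cells in the gut, which the design names, was not tested, and sex-linked transcripts cannot decide it. Their other transcripts were close to those of the Xist-bearing libraries. Correlations of log2 CPM across genes were 0.956 to 0.961 within CD8αα from CD4 and 0.958 to 0.967 within CD8αα from CD8αβ. With their companion groups they were 0.810 to 0.845 and 0.804 to 0.839. The likeness argues against a change of T cells in these 2 libraries alone.

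Transcripts of Ppia and Rps6, which have many near-identical copies, stood far higher in CD8αβ IEL replicate 1, with Ppia at 1774 CPM there against 9.38 to 29.8 in the other 11 libraries and Rps6 at 1169 against 10.8 to 26.0. A general rise of ribosomal protein transcripts was argued against, because their log2 ratios to the rest of the group had an interquartile range of 2.098, above 0.206 to 1.44 in other libraries. Another assignment of reads with several matches in this library stays open. Rows of 134 processed pseudogenes had a median log2 ratio of −1.16 there, below the −0.31 to 0.78 elsewhere. For 266 genes with a named pseudogene it was 0.178, only slightly above the −0.39 to 0.170 elsewhere. The pseudogene rows thus stood apart and the genes with a named pseudogene hardly did, so the 2 values do not decide. Nor do they show whether this library or the other 11 assigned such reads otherwise. No biological explanation was tested.

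Interferon-stimulated transcripts were lower in the CD4 progeny in both comparisons of the progenies, list calls that were lost with an estimated correlation (adjusted p = 0.506 between the CD8αα groups and 0.460 between CD4 IEL and CD8αβ IEL). Between the CD8αα groups, RNA of myeloid cells was argued against as the source, since the myeloid list had a median of 0.30 where the interferon list had −1.75. RNA of epithelial cells stays open there, because the epithelium list had a median of −0.53 (quartiles −1.13 and 0.03). Its median log2 CPM was 2.26, 4.65 and 3.19 in CD8αα from CD8αβ replicates 1 to 3 and 3.56, 3.87 and 3.30 in CD8αα from CD4. Replicates 1 and 3 of CD8αα from CD8αβ were thus below every library of CD8αα from CD4, and replicate 2 was above them. Between CD4 IEL and CD8αβ IEL such RNA stays open, because the myeloid median was −1.11 and the epithelial median −1.84. The TCRβ gate should remove those cells. Single markers did not peak with Ifit3. CD8αβ IEL replicate 3 had Ifit3 at 605 CPM, with Fabp1 at 17.3, Cd74 at 221 and Lyz2 at 5.93. Fabp1 (72.8) and Cd74 (509.7) were highest in CD8αβ IEL replicate 2, where Ifit3 was at 272. Lyz2 (21.4) was highest in CD4 IEL replicate 2, where Ifit3 was at 17.4. A day or host shared by each progeny cannot be told apart from the progeny (median −1.71 between CD4 IEL and CD8αβ IEL), because the labels give no day or host. A response that differs with the T cells transferred, which the design names, is also open.

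Per library, the median log2 CPM of the interferon list was 6.96, 7.79 and 8.60 in CD8αβ IEL replicates 1 to 3, 5.04, 6.49 and 7.25 in CD8αα from CD8αβ, 5.93, 5.83 and 5.10 in CD4 IEL and 4.36, 4.78 and 4.70 in CD8αα from CD4. Traces of Xist in CD4 IEL and CD8αβ IEL were at 15.2 and 36.4 CPM in CD4 IEL replicates 1 and 2 and at 6.93 and 13.01 CPM in CD8αβ IEL replicates 1 and 3, whose numbers are those of the Xist-bearing libraries labelled CD8αα of the same progeny. In CD4 IEL replicate 3 and CD8αβ IEL replicate 2 Xist was at 0 and 0.528 CPM.

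For the 4 pairwise comparisons the 10 splits of 6 libraries are too few for a share under 0.05. By edgeR the real counts were 3597, 3939, 547 and 3655, and the highest of the other splits was 0 in each (567, 1042, 945 and 1296 genes at an unadjusted p under 0.05, against 4905, 5069, 2373 and 5176 in the real splits). Among 100 regroupings of the 12 libraries, 1, the real one, reached the count for any difference (6587, highest other 368). A random division of 12 independent libraries was thus excluded for it. The regroupings did not keep same-numbered libraries together, so they do not exclude hosts, days or sex shared by libraries as the source. The real one alone also reached the counts for the shared change (2266, highest other 0) and for the progeny difference seen both between CD4 IEL and CD8αβ IEL and between the CD8αα groups (335, highest other 0). In 0 of the 99 other regroupings did both comparisons of either overlap call a gene, which sets the overlap to 0, so these regroupings do not test the 2 overlaps. For the number of called lists, 12 of 100 regroupings gave 67 or more (highest other 84), so chance was not excluded.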
